A study of Mus musculus with 4 samples.

How the data were processed

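The series measured messenger RNA by sequencing in regulatory T cells (Treg cells, the Foxp3-expressing CD4 T cells that restrain other immune cells) taken from spleen and peripheral lymph nodes of mice. One genotype carried a Cre recombinase with yellow fluorescent protein under Foxp3 control (WT in the labels), and the other carried in addition a Ripk1 gene flanked by loxP sites, so that Cre removes the flanked part in Foxp3-expressing cells (knockout in the labels). Each genotype gave 1 library called rTreg and 1 called aTreg, so 4 libraries were compared, with 1 library per combination. The labels do not spell out r and a, which in this field stand for resting and activated Treg cells. The gate used to sort them, the number and sex of the mice and whether the rTreg and aTreg libraries of a genotype came from the same mice are not given in the sources used here.

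RNA was extracted with TRIzol and libraries were made with a SMARTer kit, per the labels' protocols. Reads were aligned with HISAT2 2.2.1 and counted with featureCounts 2.0.1 on the mouse build GRCm38, per the submitters' processing notes. The annotation and whether counting used the strand are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be separated. The deposited count table holds whole read counts for 19044 gene symbols, not normalized by the authors. A further deposited table holds variance-stabilised values of the same libraries on a log2-like scale, per the file headers. It also holds the authors' log2 fold change and its standard error, with positive values where WT is higher. Its mean over libraries of counts divided by size factors is a signal that is never negative, per the file headers. Its test statistic is a score, the deposited log2 fold change divided by its error. Its p-value and adjusted p-value are those of the authors' comparison of genotypes. DESeq2 run on the deposited counts with genotype alone gave the same log2 fold changes within 5e-07, that is, with the rTreg and aTreg libraries of a genotype as replicates of each other.

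The libraries held 20868319 counts (WT rTreg), 20633355 counts (WT aTreg), 17588754 counts (rTreg labelled knockout) and 18857718 counts (aTreg labelled knockout). The most abundant gene, Eef1a1, took between 1.04% and 1.13% of the counts of a library. A count of 0 allows a level of up to 3 counts, which is 0.143 to 0.17 CPM (counts scaled to a common library total) here. Intervals at 95% for a ratio of counts between 2 libraries are exact binomial intervals conditional on the sum. They and this limit cover counting error only, since reads copied by PCR are not independent molecules.

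Genes with a mean of at least 5 CPM over the 4 libraries were tested, which left 9680 genes holding 99.31% of all counts. Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors between 0.995 and 1.006, and log2 CPM was computed with a prior count of 2. The counting intervals, and the ratios of genes below the level minimum, use counts without this prior count. At few counts a log2 ratio can therefore lie off the center of its interval. Each contrast of 2 libraries has no replicate, so it was given as log2 ratios and as the number of genes at least 2-fold apart, with no p-value. Genes were tested with edgeR's quasi-likelihood method on the counts with state and genotype as additive terms over the 4 libraries, which leaves 1 residual degree of freedom, at a Benjamini-Hochberg adjusted p of 0.05. In this design any difference of the genotype effect between states enters the error, and the error of the genotype effect comes from pairs of states. edgeR also draws each gene's error toward that of other genes, with a prior weight of 11.8 degrees of freedom against 1. A gene's own difference between states thus enters its error only in small part, and a gene with a large one can still have a small p. The error need not hold the spread between mice, so the p-values measure only the spread between these libraries. In the text a gene "rose" or "fell" only where this test called it. Medians of gene lists were placed among 10000 random lists of the same size matched on mean expression in 20 bins.

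Groups, tests, alternatives, the 31 gene lists and the rule for naming genes were fixed before the data were examined. The rule took Ripk1, the 8 highest and 8 lowest genes of each contrast, the 10 genes per direction at least 2-fold apart in both states or both genotypes with the largest smaller ratio, and the 10 called genes per direction with the largest change. It further took the 4 list members with the largest ratio in a contrast, the 5 genes per direction whose genotype difference differed most between states, and a few single genes, among them Foxp3, Ripk3, Mlkl, Fadd, Casp8 and Cd44. Predicted genes, clones, pseudogenes, and immunoglobulin and T cell receptor genes, Igkc and Ighd among them, were left out of the parts that rank all genes. Highest and lowest genes below are therefore those among the ranked genes. Together it named 257 genes, of which some are not reported here. Of the members of the marker lists below the level minimum, only Cd8a, Klrb1c, Gzmk and Hba-a1 are given, as counts. For 1 list, the genes of the mitochondrial genome, no member was found in the table by the names used, and it is not analysed here. The 4 markers given as counts, with Kdm5c, Kdm6a, Ddx3x, Eif2s3x and Fasl, outside the rule, were chosen after their values were seen.

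On simulated counts with 200 changed genes of 9680, the additive test recovered 99.5% of genes changed by 1 log2 unit for the state effect and 100% for the genotype effect, with 4 and 7 false calls. At 0.5 log2 units it recovered 84.5% and 83%, with 8 and 10 false calls. The simulation used 1 dispersion for all genes, taken from the additive fit of these libraries. It held no difference of an effect between states or genotypes and no spread between mice. The false calls therefore do not measure the error rate in the real libraries. Counting noise alone, simulated 20 times per contrast, gave at most 1 gene at least 2-fold apart. Coordinates come from GENCODE M21, an annotation of GRCm38 that holds 18441 (96.8%) of the symbols. Alternatives were other normalizations, prior counts and filters, the deposited variance-stabilised values, DESeq2 1.42.0, limma-voom (limma 3.58.1), the legacy edgeR method and an adjusted p of 0.1. Fits without state, removal of a length and GC trend (mgcv 1.9.3) and removal of genes on X and Y were added after seeing the data.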

Results

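Messenger RNA was profiled in Treg cells of Foxp3-Cre mice (WT) and of Foxp3-Cre mice with a floxed Ripk1 gene, each as 1 rTreg and 1 aTreg library. RIPK1 is a kinase and scaffold protein downstream of death receptors, and RIPK3 and FADD, named in the study's title with it, act in necroptosis and in apoptosis. The design asks how Treg cells differ between states and what loss of RIPK1 changes in each. Depth ran from 17588754 to 20868319 counts per library, and between 16477 and 16977 genes had a count. Across genes, log2 CPM of rTreg and aTreg libraries correlated at r = 0.981 in WT and 0.987 between the libraries labelled knockout, and of the genotypes at 0.962 in rTreg and 0.952 in aTreg, where genes are not independent replicates. There are no replicates of any group, so intervals in brackets are 95% counting intervals only.

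Ripk1 (GRCm38 chromosome 13, 34002363 to 34037147, plus strand, protein coding) was at 83.6 CPM in WT rTreg, 77.5 in WT aTreg, 84.7 in the rTreg library labelled knockout and 80.8 in the aTreg library labelled knockout. Its log2 ratio of the library labelled knockout over WT was 0.02 [−0.08 to 0.12] in rTreg, which turned to −0.03 with upper-quartile scaling, and 0.06 [−0.04 to 0.16] in aTreg. The edgeR additive test did not call it (adjusted p = 0.675). The gene overlaps Serpinb6a on the opposite strand, the floxed exons are not given in the sources used here, and a count over the whole gene checks a deletion of part of it only weakly. The counts therefore show no sign of the deletion, and the libraries are called KO-labelled throughout, including wherever a direction is drawn from them. Foxp3, the transcription factor that defines Treg cells, was at 688, 694, 619 and 658 CPM in WT rTreg, WT aTreg, KO-labelled rTreg and KO-labelled aTreg (edgeR adjusted p = 0.179 for genotype).

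**Figure D1:**
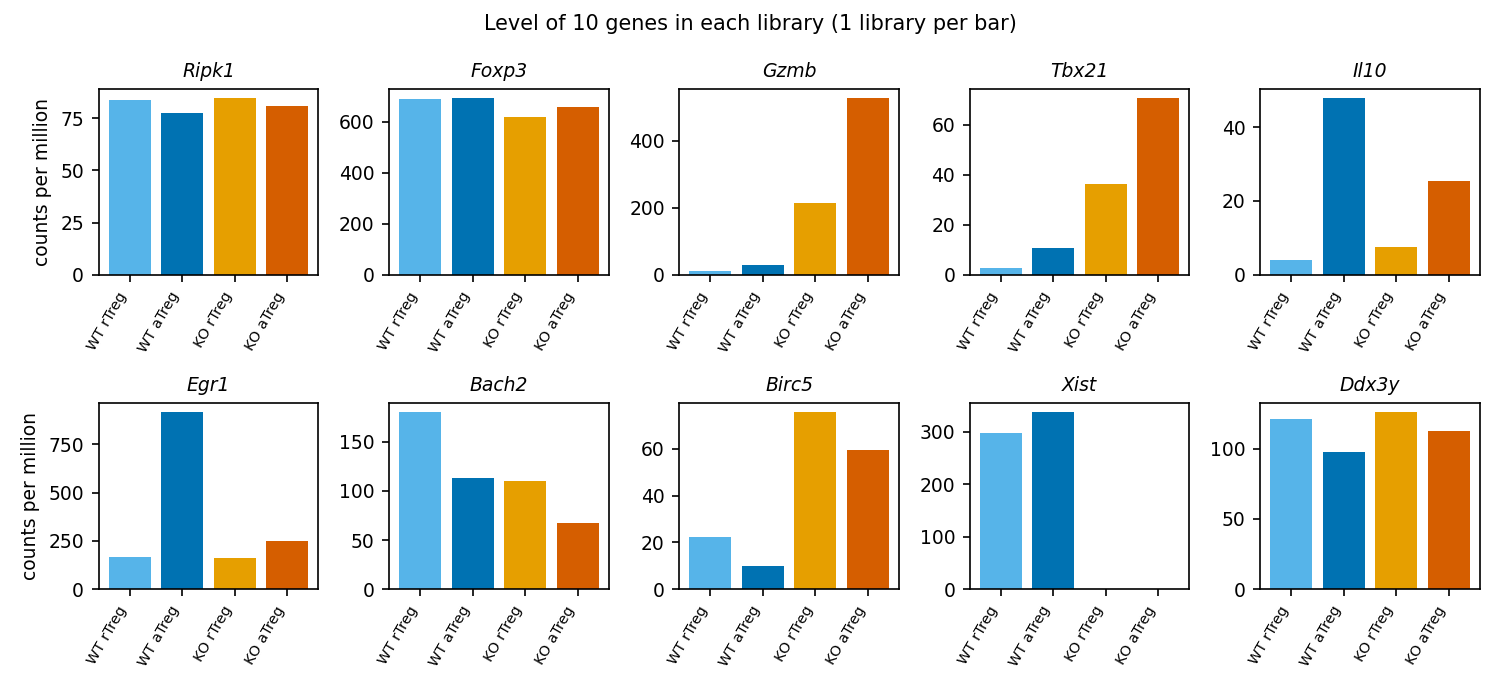
Level of 10 genes in CPM (y axis, from 0, a scale per gene) in each of the 4 libraries, 1 library per bar and no error bars. Ripk1 lies between 77.5 and 84.7 CPM in every library, Gzmb reaches 528 CPM in KO-labelled aTreg against 11.5 CPM in WT rTreg, and Xist is at 0.284 and 0.213 CPM in the KO-labelled libraries.

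In WT, the median log2 ratio of aTreg over rTreg was 0.86 over activated and effector Treg genes and −0.54 over resting and lymphoid-homing genes. Lilrb4a, an inhibitory receptor, had 14 counts in rTreg and 248 in aTreg, a log2 ratio of 3.98 [3.40 to 5.07]. Asb2, a subunit of a ubiquitin ligase, was 3.69 log2 units higher [3.42 to 4.05] and Il10, an anti-inflammatory cytokine, 3.53 higher [3.24 to 3.90]. Lilrb4b (3.03), Sccpdh (2.99), Hic1 (2.63), the long noncoding RNA Miat (2.60) and the chemokine Ccl5 (2.52) followed. The lowest were Depdc1b (−1.56), Vmn2r97 (−1.55), Ska1 (−1.54), Cdhr3 (−1.51), Acvrl1 (−1.48), Cdca5 (−1.48), Sox4 (−1.46) and Cnn3 (−1.44), of which Ska1 and Cdca5 act in mitosis. At least 2-fold apart were 251 genes, 181 higher and 70 lower in aTreg. Between the authors' deposited variance-stabilised values, which compress low genes, 33 were (30 higher, 3 lower).

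In the KO-labelled pair the same contrast was led by Asb2 (3.04), Miat (2.93), the gelatinase Mmp9 (2.89), Lilrb4a (2.77), Ifitm1 (2.46), Lilrb4b (2.35), the inhibitory receptor Pvrig (2.26) and the hypoxia-response factor Epas1 (2.07). Among the lowest were Sox4 (−1.35), Vmn2r97 (−1.32), Ccr10 (−1.23), Ly6c1 (−1.15), Cyp2d22 (−1.09), Ntn4 (−1.07) and Atp1b1 (−1.07). At least 2-fold apart were 105 genes, 92 higher and 13 lower in aTreg, against 17 (16 higher, 1 lower) between the deposited variance-stabilised values. Of all genes, 72 were at least 2-fold apart in the same direction in both genotypes (65 higher, 7 lower), where independent lists would share 1.72 and 0.094, and 10 were between the deposited variance-stabilised values. No gene was at least 2-fold apart in opposite directions, and the log2 ratios correlated at r = 0.651 across genes. Besides Asb2, Lilrb4a, Lilrb4b, Miat, Mmp9, Pvrig, Ccl5 and Il10, the genes highest in both included Csf1, a macrophage growth factor (1.73 in WT and 2.05 in the KO-labelled pair), and Il1r2, a decoy receptor for interleukin-1 (2.28 and 1.65). Among those lower in both were Sox4, Vmn2r97, Ntn4, Sgk3, Tdrp and Atp1b1.

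Over both genotypes, edgeR's additive test called 1275 genes for state, 762 higher and 513 lower in aTreg, of which 130 (114 higher, 16 lower) changed at least 2-fold. Asb2 rose by 3.35 log2 units (SE 0.140, edgeR adjusted p = 5.09e-08), Lilrb4a by 3.15 (SE 0.238, 4.37e-06) and Il10 by 2.66 (SE 0.276, 4.94e-05). Sox4, a transcription factor gene, fell by 1.42 (SE 0.125, edgeR adjusted p = 1.43e-05). DESeq2 with the same terms called 423 genes. Reads of Lilrb4a and Lilrb4b, close relatives, may be exchanged between them by counting, so their separate values are uncertain.

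Of 40 measured activated and effector Treg genes, 35 rose in aTreg and 1, Ccr10, fell (37 and 1 adjusted over the list alone), and the others, among them Irf4 and Lgals3, did not pass. The list's median log2 ratio was 0.86 in WT and 0.69 in the KO-labelled pair, both above all 10000 random lists. The inhibitory receptor Lag3 had ratios of 1.68 and 1.56, the integrin Itgae 1.46 and 0.73, Gzmb 1.35 and 1.30 and the immunoregulatory gene Fgl2 1.79 and 0.95. Of 19 resting and lymphoid-homing genes, 17 fell and none rose, the same numbers adjusted over the list alone, with medians of −0.54 and −0.49. Bach2, a repressor of effector genes, had ratios of −0.67 and −0.71, Satb1 −0.84 and −0.44 and Dapl1 −1.19 and −0.88. Of 24 Treg identity genes, 10 rose and 3 fell (14 and 4 adjusted over the list alone). Penk (2.48 and 1.37), Cd83 (1.71 and 0.55) and Nt5e (0.72 and 0.37), the ectoenzyme CD73, rose, Gpr83 fell (−0.55 and −0.59), and Foxp3 did not pass (0.01 and 0.09).

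Early-response and helper T cell genes were also higher in aTreg by their list medians. Of 15 T cell receptor early-response genes, 8 rose and none fell (10 and 0 adjusted over the list alone), with medians of 0.43 in WT and 0.23 in the KO-labelled pair. Egr1 had ratios of 2.48 and 0.62, Egr3 1.21 and 0.37 and Nr4a1 0.81 and 0.23. Of 19 immediate early and heat shock genes, which also respond to handling of cells, 9 rose (10 rose and 2 fell adjusted over the list alone). Among them were Fos (1.10 and 0.41), Fosb (1.06 and 0.42) and Hspa1b (0.94 and 0.93). Of 27 NF-kappaB target genes, 12 rose and 1, Irf1, fell (16 and 1 adjusted over the list alone), with Tnf at 1.55 and 0.77 and Icam1 at 0.74 and 0.32. Of 13 helper T cell cytokine and lineage genes, 8 rose and none fell over all genes and over the list alone, with Tbx21 at 1.92 and 0.95 and Ifng at 1.04 and 1.15. Of 23 chemokine and trafficking receptor genes, 13 rose and 5 fell (14 and 5 adjusted over the list alone), with Ccr9 at 1.08 and 1.55 and Cxcr3 at 1.33 and 0.39.

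Cell cycle and type I interferon-stimulated genes were lower in aTreg by their list medians. Of 44 cell cycle genes, 11 fell in aTreg and none rose (22 and 0 adjusted over the list alone), with a median of −0.71 in WT and −0.09 in the KO-labelled pair. The cyclin Ccna2 had ratios of −1.39 and −0.31 and the survivin gene Birc5 −1.15 and −0.35. Of 28 type I interferon-stimulated genes, 12 fell and none rose (14 fell and 1 rose adjusted over the list alone), with Oas2 at −0.79 and −0.58 and Rsad2 at −0.67 and −0.31. Of 22 interferon-gamma response genes, 2 rose (Cxcl10 and Irf8) and 3 fell (2 and 4 adjusted over the list alone), Irf1, Irgm1 and Iigp1. Of 21 glycolysis genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone), with Hk2 at 0.71 and 1.10. Of 35 oxidative phosphorylation genes, Cox8a rose and Atp5a1 fell, and none passed adjusted over the list alone. Of 21 cholesterol synthesis genes, Sc5d fell (−0.32 and −0.31) and none rose, and 1 fell adjusted over the list alone. None of 54 cytosolic ribosomal protein genes passed either way.

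The libraries labelled knockout had more mRNA of Gzmb, Tbx21 and Il12rb2 and less of Itgb8 in both states. Gzmb, a cytotoxic granule protease (chromosome 14, 56258838 to 56262260, minus strand), was 18.5-fold higher in rTreg (log2 4.21 [4.03 to 4.42]) and 17.8-fold higher in aTreg (4.15 [4.04 to 4.28]). Tbx21, which encodes T-bet, the transcription factor of type 1 helper cells (chromosome 11, 97098071 to 97115331, minus strand), was higher by 3.67 [3.33 to 4.14] and 2.70 [2.51 to 2.93]. Il12rb2, a chain of the interleukin-12 receptor (chromosome 6, 67291318 to 67376188, minus strand, overlapping Serbp1 on the opposite strand), was higher by 3.58 [3.04 to 4.48] and 5.56 [4.85 to 7.44], from 19 and 6 counts in WT. Itgb8, an integrin chain that activates TGF-beta (chromosome 12, 119158022 to 119238802, minus strand), was lower, at −1.61 [−1.861 to −1.381] and −1.80 [−1.998 to −1.622].

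In rTreg, 460 genes were at least 2-fold apart between genotypes, 330 higher and 130 lower in the KO-labelled library. The highest of the ranked genes, which leave out Igkc, were Gzma (4.31), Gzmb, Serpina3f (3.84), Tbx21 and Il12rb2. The guanylate-binding protein gene Gbp2b (3.24), the interferon-induced Ifitm2 (3.15) and Havcr2 (3.12), the inhibitory receptor TIM-3, followed. After Xist (−9.60), the lowest were Chdh (−2.21), Tmem121b (−1.99), Camk2n1 (−1.92), Kcnf1 (−1.91), Ryr2 (−1.69), Mapk12 (−1.67) and Rgs9 (−1.66). Between the authors' deposited variance-stabilised values, 84 genes were at least 2-fold apart (74 higher, 10 lower).

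In aTreg, 592 genes were at least 2-fold apart, 382 higher and 210 lower in the KO-labelled library. The highest of the ranked genes, which leave out Igkc, were Il12rb2, Ifitm1 (4.72), Ifitm2 (4.54), Gzmb, Havcr2 (4.02) and Gzma (3.51). The granule protein gene Nkg7 (3.19) and Lgals3 (3.03), which encodes a galectin, followed. After Xist (−10.06) the lowest were Npas4 (−2.38), Ryr2 (−2.17), Gucy1a1 (−2.17), Chdh (−2.06), Fam43a (−2.06), H2-Ob (−2.02) and Lzts2 (−2.02). Between the authors' deposited variance-stabilised values, 164 genes were (129 higher, 35 lower).

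The genotype ratios of the 2 states, which share no library, went together across genes. In both states 346 genes were at least 2-fold apart in the same direction, 260 higher and 86 lower, where independent lists would share 13 and 2.82, and 63 were (54 higher, 9 lower) between the deposited variance-stabilised values. No gene was at least 2-fold apart in opposite directions. Log2 ratios correlated at r = 0.868 across genes (0.863 without Xist), as the plot of both genotype ratios shows. Besides Gzmb, Gzma, Il12rb2, Tbx21, Havcr2 and Nkg7, the genes higher in both were led by Ifitm2, Serpina3f, the peptide transporter Slc15a3 (2.65 and 2.68) and Hip1 (2.94 and 2.57). Besides Xist, Chdh, Kcnf1, Ryr2, Rgs9, Tmem121b and Itgb8, the genes lower in both were led by H2-Ob, a class II antigen-presentation gene, Dtx4 (−1.61 and −1.88) and Ttc28 (−1.53 and −1.78). Whether both libraries of a genotype came from the same mice is not given, so the states need not be separate animals.

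**Figure D2:**
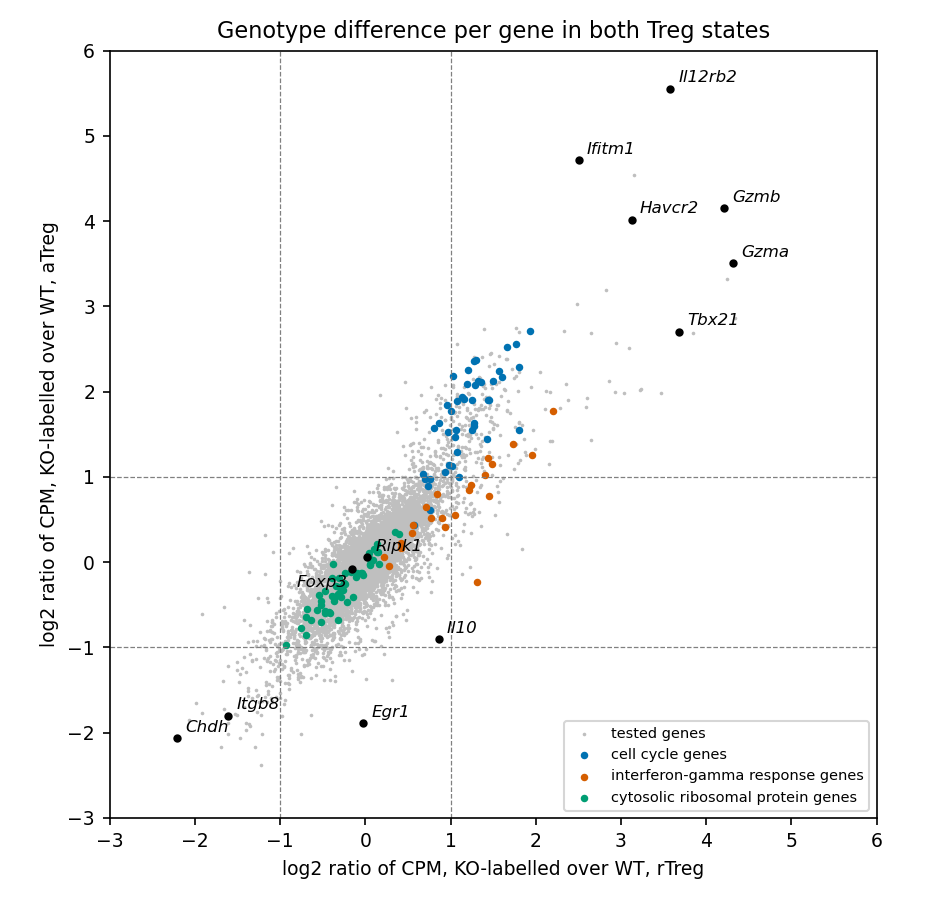
Each point is 1 of 9680 tested genes, with its log2 ratio of CPM, KO-labelled over WT, in rTreg (x axis) and aTreg (y axis). Dashed lines stand at a 2-fold difference, colours mark cell cycle, interferon-gamma response and ribosomal protein genes, and Xist (−9.60 and −10.06) lies outside the axes.

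For genotype, edgeR's additive test called 4589 of the 9680 tested genes, 2368 higher and 2221 lower in the KO-labelled libraries. Of those called, 486 (344 higher, 142 lower) changed at least 2-fold. Counts of called list members given below stand against this share of all tested genes. Gzmb rose by 4.19 log2 units (SE 0.0741, edgeR adjusted p = 4.85e-13) and Tbx21 by 3.08 (SE 0.175, 9.88e-08). Itgb8 fell by 1.72 (SE 0.114, edgeR adjusted p = 2.1e-07). The error of this test is the spread of state pairs, largely pooled over genes, with a biological coefficient of variation of 6.66%. With the states as replicates that coefficient was 13.7%, edgeR called 1641 genes, all of them called in the same direction by the additive test, and DESeq2 with the additive terms called 2527. The authors' deposited table has 2060 genes with an adjusted p under 0.05, 1192 higher and 868 lower in the KO-labelled libraries. Of these, 1909 were among the tested genes, and the additive test called all 1909 in the same direction. Both overlaps come from the same libraries, and the additive test has the smaller error, so they are no independent check of the calls.

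Cell cycle and interferon-gamma response genes were higher together in the KO-labelled libraries. All 44 measured cell cycle genes rose, over all genes and adjusted over the list alone, with a median log2 ratio of 1.18 in rTreg and 1.81 in aTreg, above all 10000 random lists. Birc5 had ratios of 1.77 and 2.57, the cyclin Ccnb2 1.66 and 2.53, the replication-licensing gene Cdc6 1.80 and 2.29 and the transcription factor gene E2f8 1.93 and 2.71. Of 22 interferon-gamma response genes, 19 rose and none fell (19 and 0 adjusted over the list alone), with medians of 0.99 and 0.60. They included Iigp1 (2.21 and 1.77), Gbp3 (1.96 and 1.26), Gbp2 (1.73 and 1.39) and Irf8 (1.44 and 1.22), while Cxcl10 (1.31 and −0.23) and Gbp9 (0.28 and −0.05) did not pass. Gbp2 and Gbp2b, Ifitm1 and Ifitm2, and Serpina3f and its neighbours in its family are close relatives, so reads may be split between them. Of 28 type I interferon-stimulated genes, in contrast, 11 rose and 10 fell (11 and 10 adjusted over the list alone), with medians of 0.09 and −0.06. Oasl1 (−1.27 and −1.76), Rsad2 (−1.16 and −0.80) and Usp18 (−0.71 and −0.92) fell.

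Effector and resting genes differed with genotype as well. Of 40 activated and effector Treg genes, 27 rose and 3 fell in the KO-labelled libraries (27 and 3 adjusted over the list alone), with medians of 0.71 and 0.63. Cxcr3, a chemokine receptor of type 1 responses, had ratios of 2.93 and 1.99, Itgae 0.89 and 0.17 and Il1r2 1.58 and 0.95, whereas Cd44 fell (−0.25 and −0.32) and Lag3 did not pass (0.27 and 0.15). Of 19 resting and lymphoid-homing genes, 14 fell and 1, Igfbp4, rose (14 and 1 adjusted over the list alone), with Il6ra at −0.79 and −1.02, Bach2 at −0.71 and −0.74 and Bcl2, a survival gene, at −0.60 and −0.69. Of 24 Treg identity genes, 10 rose and 9 fell (10 and 9 adjusted over the list alone), with Socs2 (1.18 and 0.88) and Entpd1 (0.71 and 0.89), the ectoenzyme CD39, up and Nt5e (−1.02 and −1.36) and Cd83 (−0.64 and −1.79) down. Of 13 helper T cell genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone). Ifng was higher by 1.94 and 2.06 from 69 and 141 counts in WT, Il18r1 by 0.86 and 0.93, and Bcl6 was lower, at −0.48 and −1.13.

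**Figure D3:**
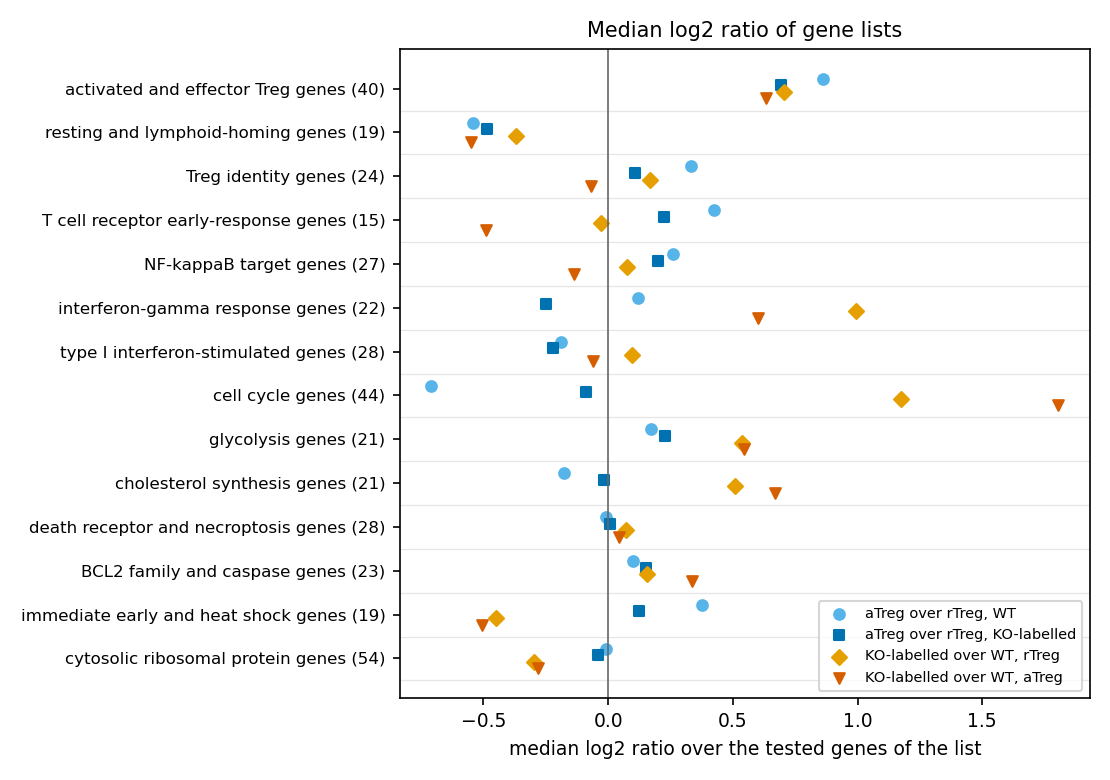
Median log2 ratio of CPM (x axis) over the tested members, whose number stands in parentheses, of 14 gene lists fixed before the data were examined (y axis), for the state contrast in each genotype and the genotype contrast in each state. The cell cycle list has medians of −0.71 and −0.09 for state and of 1.18 and 1.81 for genotype.

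Glycolysis and cholesterol synthesis genes were mostly higher in the KO-labelled libraries. Of 21 glycolysis genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with medians of 0.54 in both states and Tpi1 at 1.41 and 1.47, Slc16a3, a lactate exporter, at 0.85 and 1.41 and Pgam1 at 1.01 and 0.84. Of 21 cholesterol synthesis genes, 15 rose and none fell (16 and 0 adjusted over the list alone), with Idi1 at 1.29 in both states and Hmgcs1 at 0.72 and 0.90. Of 35 oxidative phosphorylation genes, 18 rose and 1, Ndufa2, fell (18 and 1 adjusted over the list alone), with Cox5a at 0.63 and 0.83. Cytosolic ribosomal protein genes, a list fixed as a check of the samples, went the other way. For them a difference between the libraries themselves was not tested apart from one of genotype. Of 54, 34 fell and 2 rose (35 and 3 adjusted over the list alone), with medians of −0.30 and −0.28 and with Rps16 at −0.93 and −0.97 and Rps28 at −0.75 and −0.77.

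T cell receptor early-response genes were lower in KO-labelled than in WT aTreg by their list median, which was near 0 in rTreg. Of 15 T cell receptor early-response genes, 8 fell and 1, Tnfrsf9, rose (8 and 1 adjusted over the list alone), with medians of −0.03 in rTreg and −0.49 in aTreg. Nr4a2 had ratios of −0.90 and −1.36, Spry1 −0.72 and −1.22 and Egr1 −0.03 and −1.89. Immediate early and heat shock genes, which mark handling as well as signalling, were lower beside them, with 13 of 19 falling and none rising (14 and 0 adjusted over the list alone) and medians of −0.45 and −0.51. They included the chaperone gene Hsph1 (−1.21 and −1.63), Btg1 (−0.79 and −0.96) and Fos (−0.52 and −1.21). Of 27 NF-kappaB target genes, 9 rose and 8 fell (9 and 9 adjusted over the list alone), with Bcl3 (0.80 and 0.82) and Icam1 (1.04 and 0.62) up and Tnfaip3, which encodes the NF-kappaB inhibitor A20, down (−0.60 and −0.58). Of 23 chemokine and trafficking receptor genes, 9 rose and 5 fell (9 and 8 adjusted over the list alone), with Ccr2 at 1.14 and 1.27.

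Of 28 death receptor and necroptosis genes above the level minimum, 6 rose and 4 fell in the KO-labelled libraries, the same adjusted over the list alone. None was 2-fold apart in any contrast. Over all genes a larger share was called, 4589 of 9680. The list's median log2 ratios of 0.07 in rTreg and 0.04 in aTreg lay at the 84.55 and 72.77 percentiles of random lists, so the list did not stand out. Ripk3 rose (log2 0.28 in rTreg and 0.50 in aTreg, edgeR adjusted p = 0.00124) and Fadd rose (0.86 and 0.68, edgeR adjusted p = 0.00125), while Casp8 did not pass (0.08 and −0.04, edgeR adjusted p = 0.771). Zbp1, a nucleic acid sensor that acts through RIPK3, rose (0.85 in both states). Mlkl, the executioner of necroptosis, lay below the level minimum with 35 and 38 counts in WT and 71 and 94 in the KO-labelled libraries, and had log2 ratios of 1.27 [0.67 to 1.90] in rTreg and 1.44 [0.88 to 2.02] in aTreg. The authors' deposited table, whose log2 fold changes DESeq2 without state matched, gives Mlkl a log2 ratio of WT over the KO-labelled libraries of −1.37 (adjusted p = 0.0262). By that comparison Fadd was at −0.77 (adjusted p = 0.0170), and Ripk3, at −0.40 (adjusted p = 0.0537), did not pass 0.05. The call of Ripk3 thus depends on the additive test. Fasl, the death ligand gene and the other member below the minimum, was at −1.21 [−1.72 to −0.72] and −0.36 [−0.77 to 0.04], and was named after its values were seen. For state, 3 of these genes rose and 2 fell over all genes and over the list alone, with Tnfrsf1b at 0.99 and 0.57. Of 23 BCL2 family and caspase genes, 12 rose and 6 fell with genotype (13 and 6 adjusted over the list alone). The inflammatory caspase genes Casp1 (1.87 and 1.29) and Casp4 (1.48 and 1.23) were up. Pro-death genes went both ways, with Pmaip1 (0.82 and 0.65) up and Bcl2l11 (−1.10 and −0.90) and Bmf (−1.10 and −1.63) down. In the authors' deposited comparison the pro-death genes Bak1 and Bbc3 had log2 ratios of WT over the KO-labelled libraries of −1.04 and 0.82, again in opposite directions. For state, 5 rose and 2 fell (8 and 3 adjusted over the list alone).

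Some markers of other cells moved beside the genotype. The antibody light chain gene Igkc, the only measured plasma cell marker, rose, with 21 and 31 counts in WT and 365 and 300 in the KO-labelled libraries. Of 4 measured B cell markers, Cd74 (log2 2.19 and 1.43), Ighm (1.09 and 0.25) and Ighd (1.84 and 0.15) rose, the same 3 adjusted over the list alone, whereas Cd79b did not pass. Of 4 measured CD8 T and NK cell markers, Gzma, Prf1 (1.08 and 2.56) and Nkg7 rose, the same 3 adjusted over the list alone, and Cd8b1 did not pass (0.27 and 0.19). Below the level minimum, Cd8a had 9, 2, 14 and 15 counts in WT rTreg, WT aTreg, KO-labelled rTreg and KO-labelled aTreg, Klrb1c 13, 48, 5 and 26, Gzmk 0, 2, 36 and 112 and the red cell gene Hba-a1 5, 14, 131 and 136. Of 7 conventional CD4 T cell markers, Pde3b, Themis and Igfbp4 rose and Il7r and Cd40lg fell, over all genes and over the list alone. Of 5 myeloid markers none passed for genotype, nor did the single measured dendritic cell (Bst2), erythroid or platelet (Itga2b) and stromal or endothelial (Pecam1) markers. For state, Nkg7 rose (2 CD8 T and NK cell markers rose and 1 fell adjusted over the list alone), the myeloid marker Cybb rose, Ms4a6c and Pecam1 fell, Cd40lg and Cd226 rose and Igfbp4 and Tgfbr3 fell among conventional CD4 markers, and no B or plasma cell marker passed over all genes, against 4 B cell markers that rose adjusted over the list alone.

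Sex-linked genes separated the genotypes. Xist, the noncoding RNA of the inactive X chromosome in female cells (chromosome X, 103460366 to 103483254, minus strand, overlapping Tsix), had 6271 and 6955 counts in WT rTreg and aTreg and 5 and 4 counts in the KO-labelled libraries. The Y-linked Ddx3y had 2542 and 2007 counts in WT and 2218 and 2106 in the KO-labelled libraries, so both WT libraries held Xist and Y-linked RNA. Eif2s3y (0.41 and 0.59) and Kdm5d (0.41 and 0.43) rose with genotype and Xist fell, 2 and 1 of 5 genes over all genes and over the list alone, and for state Eif2s3y and Ddx3y fell. Genotype and the presence of Xist go together in these libraries, so every genotype difference given here is also one between libraries with and without Xist.

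For some genes the genotype difference was not the same in both states. Il10 was higher in the KO-labelled library in rTreg (0.86 [0.47 to 1.29]) and lower in aTreg (−0.90 [−1.07 to −0.75]). Egr1 was at 164 CPM in WT rTreg, 916 in WT aTreg, 161 in KO-labelled rTreg and 248 in KO-labelled aTreg, a difference between the genotype ratios of −1.86. Among the ranked genes, which leave out immunoglobulin genes such as Ighd, Sccpdh (−1.70), Cxcl10 (−1.53) and H2-Q10 (−1.37) had the next lowest differences. Ifitm1 (2.21), Il12rb2 (1.98), Ggt1 (1.79), Depdc1b (1.64) and Pde4a (1.49) had the highest of them. A difference of at least 2-fold was found for 78 genes, 38 higher and 40 lower in aTreg. This count was 1 between the deposited variance-stabilised values, 17 at a minimum of 20 CPM and 399 at 1 CPM. Cell cycle genes had a median difference of 0.57, T cell receptor early-response genes −0.43 and interferon-gamma response genes −0.34. With 1 library per combination these differences have no replicate check and no test.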

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

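Of the tests weighed here, those on the sex of the mice, on aTreg cells in the KO-labelled rTreg library, on rTreg cells in the KO-labelled aTreg library and on handling were chosen only after the result was seen. The test on aTreg cells replaced one fixed beforehand. The earlier one used the median excess of the KO-labelled rTreg library over the higher WT library, which is not given here.

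Named genes and list medians were picked out where 2 groups moved in opposite directions under the same contrast. For genes, both log2 values had to be at least 0.5 in size with counting intervals that exclude 0. For lists, with no minimum size, 1 median had to lie above the 97.5 percentile of random lists and the other under the 2.5 percentile. Without the minimum of 0.5, 29 named genes had opposite directions. None of these differences was tested, since each rests on 1 library per combination. Il10 had genotype ratios of 0.86 in rTreg and −0.90 in aTreg, a difference of −1.77. Il12rb2 had ratios of aTreg over rTreg of −1.36 in WT, from 19 and 6 counts, and 0.62 in the KO-labelled pair, a difference of 1.98. Prf1, which encodes perforin, had state ratios of −0.61 in WT and 0.87 in the KO-labelled pair, a difference of 1.49. Ggt1, a gamma-glutamyl transferase gene, had −1.04 and 0.75, a difference of 1.79. The median state ratio of interferon-gamma response genes was 0.12 in WT and −0.25 in the KO-labelled pair, which differ by −0.37.

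The 260 genes at least 2-fold higher in both KO-labelled libraries, such as Gzmb, Tbx21 and Il12rb2, formed the first pattern. The largest Y-linked ratio, 0.59 (the smallest was −0.01), implies a female share of the WT cells of 33.7%, if male cells of both genotypes held equal Y-linked RNA. On that assumption the loss of female cells could raise a gene by at most 0.59 log2 units. The set's median smaller ratio was 1.29 (quartiles 1.14 and 1.54). This argues against sex composition as the cause for the set, under that assumption only. X-linked genes that escape inactivation in female cells gave no single share. Kdm5c (−0.51 and −0.48) and Kdm6a (−0.49 and −0.48) were lower, Ddx3x was at −0.08 and −0.36 and Eif2s3x at −0.02 and −0.09. More cells like those of WT aTreg in the KO-labelled rTreg library could not change the aTreg ratios, so by design they cannot account for that part of the pattern. In rTreg they could raise a gene by no more than its WT difference between aTreg and rTreg. That difference had a median of −0.30 (quartiles −0.69 and 0.37) and lay under 1 for 225 of 260, which argues against such cells for the rTreg ratios of these. Of the other 35, 7 did not exceed WT aTreg, and for them only the rTreg ratio stays open. CD8 T or NK cells among the sorted cells cannot be told apart from a change within Treg cells, since Cd8a differed by as much as 3.04 in aTreg but on 2 and 15 counts (interval 0.94 to 6.21), while Cd8b1 stayed under the set's medians of 1.37 and 1.72 (upper bounds 0.55 and 0.52) and the NK gene Klrb1c was lower in both KO-labelled libraries. A response of Treg cells to the loss of RIPK1 remains a hypothesis, as do differences between mice, and Ripk1 counts give no check of it.

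The 86 genes at least 2-fold lower in both KO-labelled libraries, such as Itgb8, Chdh and H2-Ob, formed the second pattern. Removal of a smooth trend on transcript length and GC left 65 of 86 (75.6%) at least 2-fold lower in both states. That share lay between the bounds set for it. The set's medians moved only from −1.22 to −1.16 in rTreg and from −1.45 to −1.37 in aTreg, so this trend accounted for little of their size. Genes that no longer passed may have lain near the 2-fold cut, so a part of the trend in single genes was not decided. Beside Xist, 2 of these genes lay on X against 2.65 expected from the tested genes, which decides nothing for autosomal genes that female Treg cells may express more. Sex of the cells and genotype cannot be told apart for this set, because the design joins them. No other biological explanation was tested.

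The smaller difference of T cell receptor early-response genes between aTreg and rTreg in the KO-labelled pair formed the third pattern, with a median of −0.43 and 14 of 15 genes, Egr1 among them. Admixed rTreg cells in the KO-labelled aTreg library would bring state differences closer to 0. Of 59 resting and effector genes, 26 were closer to 0 in the KO-labelled pair and 12 were further from 0 by more than their counting intervals, so admixture cannot be told apart from changes within the cells, since genes moved both ways. Handling before lysis remains open, since immediate early and heat shock genes moved the same way with a median of −0.24 (quartiles −0.43 and −0.14), past −0.22, the bound set for it from the T cell receptor list. Genes such as Fos also respond to T cell receptor signals, so this value could likewise come from weaker signalling in the KO-labelled aTreg cells, which was not tested apart from handling.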

How the results depend on the processing

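Fits without state, the length and GC trend and removal of genes on X and Y were alternatives chosen after seeing the data. Values are given in the order state in WT, state in the KO-labelled pair, genotype in rTreg, genotype in aTreg, genotype in both states, state in both genotypes and difference between states, where 251, 105, 460, 592, 346, 72 and 78 genes were at least 2-fold apart. A minimum of 1 CPM gave 550, 319, 882, 1057, 555, 145 and 399 genes, and 20 CPM gave 95, 36, 234, 285, 184, 29 and 17. No minimum gave 1974, 2068, 2618, 3073, 1040, 391 and 2997, and the deposited variance-stabilised values 33, 17, 84, 164, 63, 10 and 1. The minimum sets how many low genes are tested, and variance stabilisation compresses their ratios by construction. The 1275 genes called for state became 805 without a minimum, 423 with DESeq2 and 782 after the length and GC trend was removed. The 4589 called for genotype became 2527 with DESeq2, 1641 with edgeR without state and 2060 with DESeq2 without state. The cause of these shifts in calls was not tested. Other normalizations, prior counts, limma-voom, the legacy edgeR method, an adjusted p of 0.1 and removal of X and Y kept these counts within 1.5 times, and Ripk1 stayed within its counting interval. No normalization moved the median of all genes by more than 0.1 log2 units. Of single genes, 41 of 8932 values changed sign, the largest of them 0.0435 in size by the main settings, among them Ripk1 in rTreg (−0.03 with upper-quartile scaling), and 20 of 928 list medians did, the largest 0.14 in size. The 38 higher and 40 lower genes differing between states became 40 and 39 with DESeq2 size factors, 40 and 37 with upper-quartile scaling, 28 and 26 with a prior count of 10 and 40 and 33 without X and Y. For named genes 8348 values stayed within their counting intervals and 566 moved beyond them, and 843 list medians stayed within their simulated counting spread and 85 moved. Length and GC together explained 3.96%, 11.3%, 5.79% and 4.31% of the variance of the log2 ratios in the 4 contrasts. Leaving out a library leaves the additive fit no residual degree of freedom, so it gave no value there, and the fits without state, which would keep 1, were not run without a library. No paired analysis was possible because the groups hold 1 library each and share only 1 replicate number, so no replicate block could be fitted. The additive fit pairs libraries by state and by genotype, not by mouse. Depth limits genes with few counts, such as Il12rb2 with 6 counts in WT aTreg.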

Other observations

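Of 21 unfolded protein response genes, 12 rose and 1, Dnajb9, fell in the KO-labelled libraries by the edgeR additive test (14 and 2 adjusted over the list alone), with medians of 0.28 in rTreg and 0.31 in aTreg, and none passed for state. Sdf2l1 had ratios of 0.93 and 0.99 and the protein-folding enzyme gene Pdia3 0.80 and 0.61, while the chaperone gene Hspa5 (0.23 and −0.15) did not pass. Of 18 p53 target genes, 7 rose and 7 fell (8 and 7 adjusted over the list alone) with medians of 0.08 and 0.03, and the cell cycle inhibitor Cdkn1a (1.35 and 1.30), Gtse1 (0.81 and 1.30), Btg2 (−1.09 and −1.64) and Sesn1 (−1.05 and −1.15) were among them. For state, 4 of them rose and none fell over all genes and over the list alone, with Cdkn1a at 1.06 in WT and 1.01 in the KO-labelled pair. Of 17 genes of mTORC1 and amino acid supply, 5 rose and 4 fell with genotype (6 and 5 adjusted over the list alone) and the medians were −0.04 and 0.01, with the serine synthesis genes Psat1 (0.79 and 0.81) and Phgdh (0.67 and 0.63) up and Ddit4, an inhibitor of mTORC1, down (−0.98 and −0.76). For state 2 of them, Slc3a2 and Slc1a5, rose (4 rose adjusted over the list alone).

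Of 21 genes of the TNF superfamily and its receptors, 11 rose in aTreg and none fell, over all genes and over the list alone, with Tnfrsf8 at 1.99 in WT and 1.33 in the KO-labelled pair and Tnfsf14 at 1.20 and 1.42. With genotype 5 rose and 7 fell, over all genes and over the list alone, among them Tnfrsf4 (0.49 and 0.39) up and Tnfsf14 (−0.83 and −0.61) and Tnfsf11 (−0.44 and −0.86) down. Some X-linked genes that escape inactivation in female cells were looked up after Xist had been seen. Kdm5c (−0.51 in rTreg and −0.48 in aTreg) and Kdm6a (−0.49 and −0.48) were lower in the KO-labelled libraries, Ddx3x was at −0.08 and −0.36 and Eif2s3x at −0.02 and −0.09.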
